A study of Homo sapiens with 6 samples.

How the data were processed

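Total RNA of 2 stable derivatives of the HuCCT1 cholangiocarcinoma line was hybridised to 6 single-colour Illumina bead arrays, 3 of mock cells with an empty vector and 3 of cells labelled as overexpressing WTAP, per the labels. RNA was extracted with a column kit and labelled by the manufacturer's standard protocol, per the labels' protocols. Group and array number were taken from the sample titles, which carry the numbers 4, 5 and 6 in both groups.

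The authors deposited a table of probe intensity on the linear scale that was not normalized between arrays, with a detection p-value for each probe and array, which sets its signal against the negative control probes of that array. BeadStudio 3.3 is named in the submitters' processing notes. Whether background was subtracted before is not given in the sources used here; the lowest signal on an array was 65.0 to 78.2. The authors also deposited a table of processed intensity values, whose 6 columns had medians of 196.8 each and ranked the probes of an array as the table before normalization did (Spearman correlation 1). From its values that table is on the linear scale and quantile normalized, and the unchanged ranks argue against any centring of genes. Its background treatment is not stated. It gave nearly the count of changed genes found with no background correction (2993 and 2968), so these alternatives are not independent. The processed table was used as an alternative only.

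The table before normalization held 29377 probes. The 92 that the processed table lacks, of which 1 was detected on at least 3 arrays, were used in background correction and normalization and left out of the tests. Of the other 29285, 27988 had 1 gene symbol in the platform annotation, 0 had several and 1297 had none. For 27819 of the named probes the symbol was updated by gene identifier from the RefSeq gene table of assembly GRCh38.p14. As no genome build belongs to the arrays, that table served only for names, chromosomes and the order of neighbouring genes, and no coordinates are given.

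Background was corrected and the arrays were normalized with neqc of limma 3.58.1 in R 4.3.3, that is normexp with negative control levels inferred from the detection p-values, an offset of 16, quantile normalization and log2. A probe was kept when detected (detection p under 0.05) on at least 3 arrays, which left 15830 probes, 679 of them without a gene name. Of several probes of a gene the one with the highest mean over all arrays was tested, which gave 11586 genes; 2812 genes had more than 1 detected probe, and probes of named genes that differed are given in the text. The groups were compared with lmFit and eBayes of limma, with Benjamini-Hochberg adjustment and a threshold of 0.05, and a log2 fold change of at least 1 was counted as 2-fold. Log2 fold changes are the arrays labelled WTAP minus the mock arrays, on values that hold the offset, so that changes of dim genes are understated. Of a gene detected on no array of a group the fold is given as a lower bound: the mean of the group that detected it against the mean, over the arrays of the other group, of the higher of the lowest normalized value among detected probes and the gene's own value.

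The text names WTAP, the 12 genes with the largest rises and the 12 with the largest falls among those past the threshold with groups that did not overlap (bounds were ranked in place of fitted values), up to 4 changed members of the lists of m6A factors, metalloproteinases, cathepsins, mucins, epithelial junction and mesenchymal genes, and up to 2 of other lists. This rule, the 40 gene lists, the gene and list tests and all alternatives but 1 were fixed before the data were examined. The summaries by chromosome and the tests of explanations that the closing section names as such were chosen after. Genes outside the rule are marked as named after their values were seen. The lists of metalloproteinases, cathepsins and mucins hold genes that the study is known to have followed up. Lists with at least 5 tested genes (37) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. For neighbouring genes, the 11547 tested genes placed on an autosome or the X chromosome were ordered along each chromosome and parted into 220 blocks of 50 genes, the last block of a chromosome taking the remainder, and 1000 random gene orders gave the chance values. Pairs of neighbours whose symbols share their opening 3 letters were left out of the neighbour correlation.

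Arrays with the same number deviated together: the correlations across genes of their deviations from the group means were 0.12, 0.21 and 0.23 for numbers 4, 5 and 6, against -0.20 to 0.02 for other combinations. Deviations from a group mean cancel out within the group, so positive values for some combinations push others down. The check is therefore no proof that the numbers pair the arrays. Any pairing comes from the titles, which do not say what the numbers mark. A replicate block for the number was fitted as an alternative.

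The alternatives were the replicate block, no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed table, no filter on dim probes, a stricter filter (detection p under 0.01 on all arrays of a group), all detected probes, a trended and robust variance, array weights, each array left out in turn, an adjusted p under 0.01, and for lists an estimated correlation and fry. An alternative added after the data were seen subtracted from each gene's value on the arrays labelled WTAP the median log2 fold change of the other genes of its block. The chip could not be used as a block, since no chip is named in the sources used here.

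The gene test was tested on simulated data made from the levels of these arrays and the spread of their bright probes (10 simulations of about 14432 genes, 3 arrays against 3). It called 26.0% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 94.8% of those changed 4-fold, and 4.17% of its calls were false. Over all simulations 650, 633 and 613 genes were changed by these folds, a far smaller share than the 20.4% that passed in the real data. The rates therefore need not hold for the real comparison. The list test called 50 of 50 simulated lists of 30 genes shifted by 0.5 on the log2 scale and 0 of 1000 lists without a shift, for genes simulated without correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.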

Results

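Gene expression was measured on Illumina bead arrays in HuCCT1 cells, an established human cholangiocarcinoma (bile duct cancer) line, in 2 stable derivatives. The mock cells carried an empty vector, and the other cells were labelled as stably overexpressing WTAP, a regulatory subunit of the complex that methylates adenosines in messenger RNA and a partner of splicing factors. Each group had 3 arrays, numbered 4, 5 and 6 in the labels. The labels do not say that these came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical, and the number of arrays limits the precision. The median bead signal lay between 191 and 203 on the 6 arrays, and 15071 to 16307 of the 29285 probes were detected on each (detection p under 0.05). After background correction and quantile normalization, 11586 genes were tested, each through 1 probe. Pearson correlations of the log2 values across genes were 0.988 to 0.993 within a group and 0.967 to 0.976 between groups, and the leading principal component, with 64.2% of the variance, separated the groups. The comparison addressed which transcripts differ between cells with forced WTAP expression and control cells.

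No difference in WTAP itself passed the threshold. The most abundant WTAP probe read 9.84 ± 0.06 on the log2 scale in mock cells and 9.90 ± 0.06 in the cells labelled WTAP (SD, n = 3 each), a log2 fold change of 0.06 with a standard error of 0.10 (limma, Benjamini-Hochberg adjusted p = 0.703). The 95% interval of the fold was 0.889 to 1.23. Its signal before normalization was 1067 ± 53 in mock cells and 1064 ± 54.1 in the cells labelled WTAP (SD, n = 3 each). A second detected WTAP probe had a log2 fold change of -0.01 with a standard error of 0.14, and the other 3 WTAP probes were detected on 2 of 6 arrays, on 1 of 6 and on 0. The arrays therefore showed no WTAP increase, and the direction of every change below rests on the labels alone. The positions of the probes in the transcript are not given in the sources used here. A probe outside the cloned part of WTAP would read only the cell's own transcript and would check nothing.

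The 2 lines differed in 2366 genes, 20.4% of those tested, with 1218 higher and 1148 lower in the cells labelled WTAP (limma, Benjamini-Hochberg adjusted p under 0.05). Median scaling of the arrays turned this balance to 1009 higher and 1323 lower. At least 2-fold changes were found for 467 genes, 245 higher and 222 lower, and the number of genes changed at least 2-fold was 184 with no background correction and 175 in the authors' processed table. The largest rise was that of CFAP95, a cilia and flagella associated protein, which was not detected on any mock array and was at least 41.3-fold higher (adjusted p = 1.93e-06). The largest falls were those of MMP1, the interstitial collagenase, at 33.2-fold (12.10 ± 0.47 against 7.05 ± 0.24 on the log2 scale, SD, n = 3 each, limma adjusted p = 2.47e-05), and VIM, the intermediate filament protein vimentin, at 29.8-fold (13.45 ± 0.13 against 8.55 ± 0.28, SD, n = 3 each, limma adjusted p = 3.61e-06). A second VIM probe fell by 6.52 on the log2 scale. The 3 values of a group did not overlap those of the other in 39.7% of genes, where chance gives 10%. Without 1 array the count of changed genes ranged from 1345 to 2245, and it was lowest without WTAP array 4 (1345), mock array 5 (1430), mock array 6 (1559) or WTAP array 5 (1568).

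**Figure D1:**
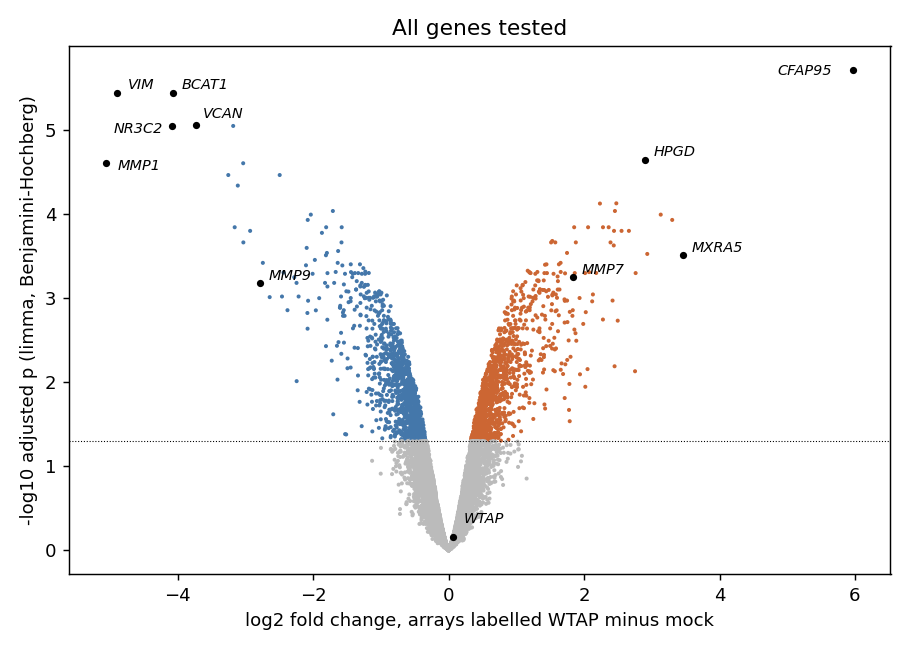
Log2 fold change of each tested gene (horizontal axis, arrays labelled WTAP minus mock) against the negative log10 of its adjusted p from limma (vertical axis), with 1218 genes higher in orange, 1148 lower in blue, the rest in grey and a dotted line at an adjusted p of 0.05. CFAP95 lies at the upper right, where its fitted value stands although no mock array detected it, VIM and MMP1 lie at the upper left, and WTAP lies near the origin with a log2 fold change of 0.06.

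Among the 12 genes with the largest rises were MXRA5, linked to matrix remodelling (log2 fold change 3.46 ± 0.27, SE), IGFL1, a secreted growth factor-like protein (3.13 ± 0.19, SE), KRT13, a keratin of stratified epithelia (2.93 ± 0.23, SE), LOXL4, a lysyl oxidase-like enzyme (2.75 ± 0.50, SE), and KISS1, the kisspeptin precursor (2.55 ± 0.18, SE). RASD2 rose 9.85-fold, and on the log2 scale MYH10, a nonmuscle myosin heavy chain, rose by 2.66, TMEM47 by 2.46, RARRES2, which encodes chemerin, by 2.45, and TAGLN, the actin-binding transgelin, by 2.44. Of these, RASD2 and TMEM47 were each detected on 1 mock array and MYH10 on 2. HPGD, which inactivates prostaglandins, was detected on no mock array and was at least 5.30-fold higher (adjusted p = 2.26e-05). Besides MMP1 and VIM, the 12 largest falls included NR3C2, the mineralocorticoid receptor (fell by 4.09), BCAT1, a branched-chain aminotransferase (at least 10.2-fold lower, adjusted p = 3.61e-06), and VCAN, the matrix proteoglycan versican (at least 8.88-fold lower, adjusted p = 8.75e-06). BCAT1 and VCAN were detected on none of the 3 arrays labelled WTAP. HYLS1 fell by 3.25, with detection on 2 arrays labelled WTAP, FAM171A1 fell by 3.18, IL37 fell by 3.11, TCN1, a vitamin-binding protein, fell by 3.03, and SCG5, a neuroendocrine secretory protein, fell by 3.03. SPANXA1 fell by 3.16 and SPANXE fell by 2.93, but these testis antigen genes are near-identical copies whose probes can cross-hybridise. The adjusted p of these 24 genes ranged from 1.93e-06 (CFAP95) to 0.00742 (LOXL4) in limma. All 3 arrays of a group lay beyond those of the other, which, like a passing adjusted p, the rule for naming them required. The second NR3C2 probe fell by 2.74, and the second probes of IL37 and TAGLN moved like the probes reported.

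**Figure D2:**
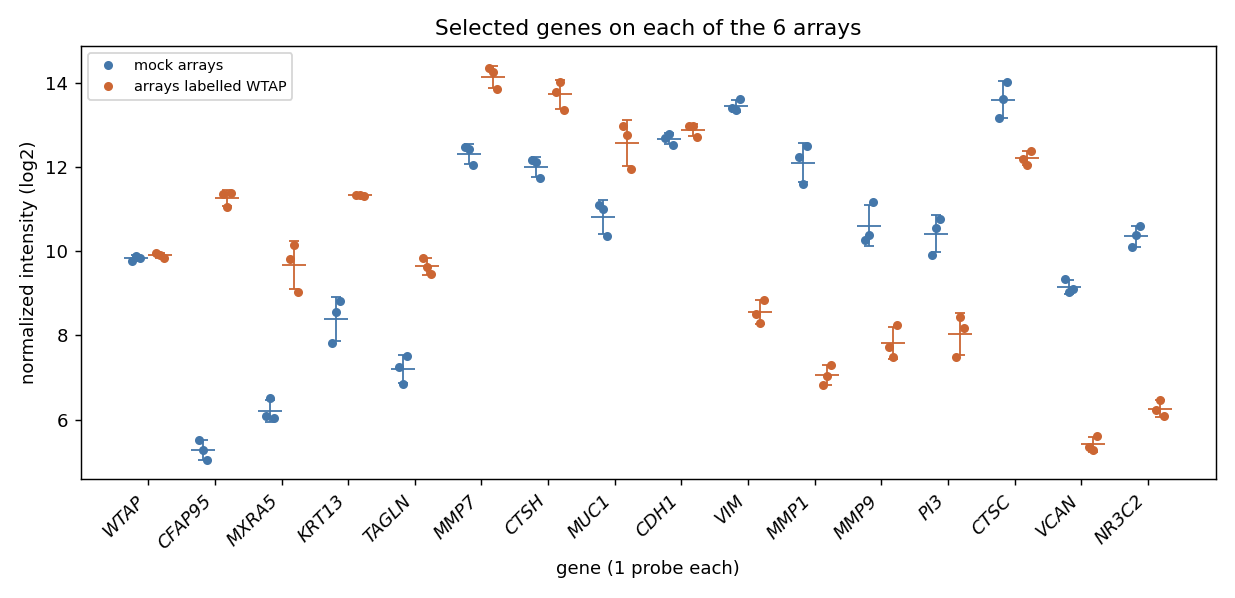
Normalized intensity on the log2 scale (vertical axis) of 16 genes on each of the 3 mock arrays (blue) and the 3 arrays labelled WTAP (orange), with 1 point per array, a horizontal mark at the group mean and bars of 1 SD. WTAP lies at 9.84 and 9.90 in the 2 groups, whereas VIM falls from 13.45 to 8.55 and CFAP95, not detected on mock arrays, reads 11.26 on the arrays labelled WTAP.

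The changed genes were not spread evenly over the chromosomes. On chromosome 10, 195 of 419 tested genes were lower and 12 higher in the cells labelled WTAP, with a median log2 fold change of -0.45, and on chromosome 13, 103 of 200 were higher and 4 lower, with a median of 0.52. Chromosome 8 had 108 genes higher and 18 lower (median 0.23), chromosome 15 had 92 higher and 24 lower (0.16), chromosome 17 had 130 higher and 23 lower (0.14), and chromosome 4 had 22 higher and 102 lower (-0.20). These 6 medians were larger than any chromosome median in 1000 random gene orders, whose highest was 0.11. Each array showed the shift: relative to the mean of all arrays, the median gene of chromosome 10 lay at 0.18 to 0.26 on the mock arrays and at -0.23 to -0.21 on the arrays labelled WTAP. On chromosome 13 the same medians were -0.28 to -0.22 and 0.24 to 0.27. Of 220 blocks of 50 or more neighbouring genes, 20 had a median beyond the highest of the random orders (0.32 in size), and these held 1083 genes, of which 503 had changed. They were not confined to the 6 chromosomes above. On chromosome 1 the block from ADORA1 to SYT14, which holds KISS1, had a median of 0.40. The chromosome 1 block from APH1A to S100A3, which holds S100A9, had 0.34, and on chromosome 12 that from LINC01559 to YARS2 had -0.38. Chromosome 1 as a whole had 219 genes higher and 63 lower (median 0.113), and chromosome 11 had 33 higher and 79 lower (median -0.113). In size both medians lay just under the highest random one of 0.115. That limit was taken over chromosomes of all sizes, down to 130 genes, and medians of few genes scatter more. For chromosomes 1 and 11, with 1195 and 698 genes, it is too wide to show that a shift is absent. VIM and FAM171A1 lie in a block of chromosome 10, from FAM171A1 to HNRNPF, in which 30 of 50 genes were lower and 1 was higher, with a median of -0.67. After subtraction of the median change of its neighbours from each gene, a setting chosen after seeing the data, 1654 genes passed the threshold, 1431 of them also before the subtraction, and VIM fell by 4.23. On chromosome 10 the count went from 207 to 78 genes, and on chromosome 13 from 107 to 44. Chromosomes and gene order were taken from the RefSeq gene table of assembly GRCh38.p14.

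**Figure D3:**
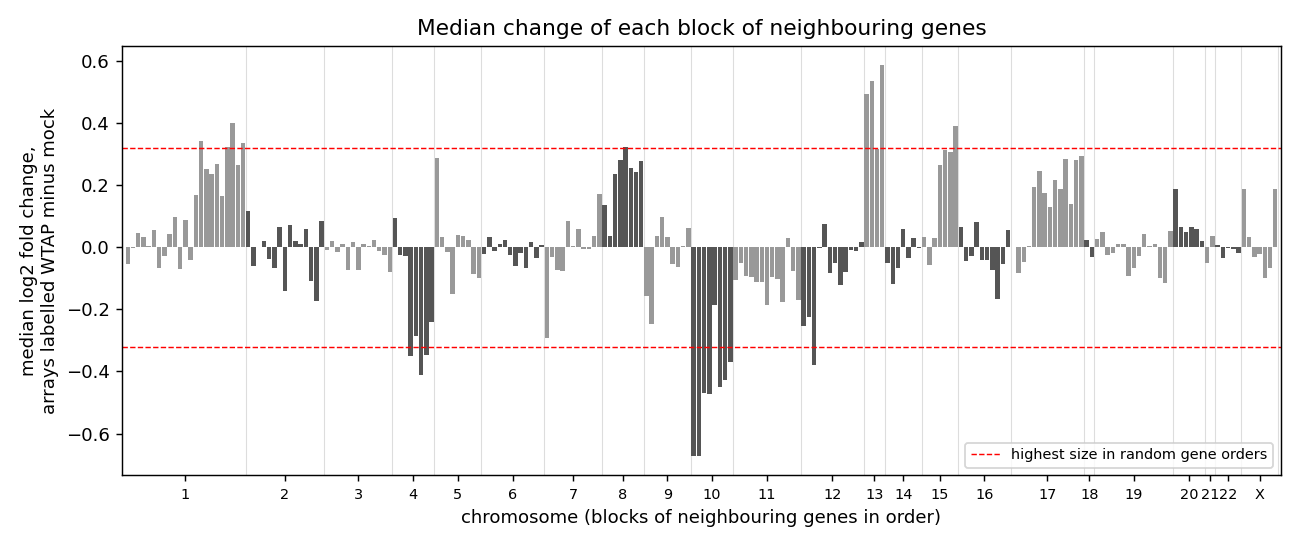
Median log2 fold change (vertical axis, arrays labelled WTAP minus mock) of each of 220 blocks of neighbouring genes, drawn in order along the chromosomes (horizontal axis), with dashed lines at the highest block median of random gene orders (0.32 in either direction). Blocks on chromosome 10 reach -0.67 and blocks on chromosome 13 reach 0.59.

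Matrix metalloproteinases, which cut extracellular matrix, moved both ways. Of 10 tested, 4 fell and 2 rose, and 6 passed when adjusted over the list alone. This list and those of cathepsins and mucins hold genes that the study is known to have followed up, so their counts are not independent evidence. Besides MMP1, MMP9, a gelatinase, fell by 2.79 (adjusted p = 0.000668, limma), MMP10, a stromelysin not detected on the arrays labelled WTAP, was at least 4.06-fold lower (adjusted p = 0.000975), and MMP14, named after its values were seen, fell by 0.72. MMP7, matrilysin, rose from 12.31 ± 0.23 to 14.14 ± 0.26 (SD, n = 3 each), a log2 fold change of 1.83 (limma adjusted p = 0.000566), with a like rise of 1.80 on its second probe. MMP28, also named after its values were seen, rose by 1.65, and a further probe of it, not detected on any mock array, was higher as well. Without mock array 4, 5 or 6 that further probe was the one tested, with a larger fitted change (limma adjusted p = 0.00139, 0.000917 and 0.00163, over 18 alternatives 2.41e-06 to 0.00324). Protease inhibitors fell more often than they rose: 9 of 22 were lower and 1 higher, and 13 passed when adjusted over the list alone. The lead ones were PI3, the elastase inhibitor elafin (fell by 2.38), and CST1, a secreted cystatin (fell by 1.59). Cell surface serine proteases and the plasminogen system split into 4 higher and 5 lower of 15 (9 when adjusted over the list alone), with rises of HTRA1 (1.52) and TMPRSS4 (1.25). The urokinase gene PLAU, named after its values were seen, fell by 0.97, and this call was lost after the subtraction of neighbouring genes (adjusted p = 0.0922, limma, over 18 alternatives 0.000299 to 0.0922).

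Of 11 cathepsins, the lysosomal proteases, 4 rose and 1 fell, with 7 passing when adjusted over the list alone. CTSH rose by 1.72 ± 0.19 (SE, limma adjusted p = 0.00108), CTSV by 0.91, CTSB by 0.82 and CTSD, named after its values were seen, by 0.54. The CTSD call was lost without mock array 4, mock array 6, WTAP array 4 or WTAP array 5 (adjusted p = 0.0591, 0.0650, 0.0764 and 0.0665, limma, over 18 alternatives 0.00283 to 0.0764). CTSC fell by 1.39, while its 3 other probes fell by 0.43 to 0.60. Of 4 mucins tested, 3 rose and 0 fell (4 when adjusted over the list alone): MUC1 by 1.75, MUC20 by 1.59 and MUC16 by 0.68. The MUC16 call (adjusted p = 0.0401) was lost without mock array 4, 5 or 6 (0.0596, 0.116 and 0.0659), without WTAP array 4 or 5 (0.120 and 0.0994) and with no filter on dim probes (0.0649, limma, over 18 alternatives 0.0103 to 0.120). MUC1 lies in a block of chromosome 1 with a median of 0.25 and CTSH in a block of chromosome 15 with a median of 0.31. Both passed after subtraction of their neighbours (limma adjusted p = 0.0131 and 0.00308).

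Mesenchymal and epithelial genes did not move as 2 opposed groups. Of 19 mesenchymal genes and regulators of the epithelial to mesenchymal transition, VIM fell and 4 rose (5 when adjusted over the list alone): TAGLN (2.44), the collagen cross-linking enzyme LOX (1.34), S100A4 (1.01) and COL1A1 (0.74). The median of this list was -0.06 and its mean -0.0027, while its camera direction was up. The S100A4 call was lost after the subtraction of neighbouring genes (adjusted p = 0.0597, limma, over 18 alternatives 0.000914 to 0.0597). A second S100A4 probe, to which the subtraction was not applied, rose by 1.56 (adjusted p = 0.0029, limma over all detected probes). Of 30 epithelial junction genes, 6 rose and 3 fell (12 when adjusted over the list alone). The tight junction genes CLDN3 and CLDN2 rose by 1.78 and 1.11, each detected on 2 mock arrays, the epithelial transcription factor ELF3 rose by 1.24, and CLDN1 fell by 1.18. The CLDN3 call was lost without WTAP array 4 or 5 (adjusted p = 0.0785 and 0.0655, over 18 alternatives 0.00144 to 0.0785) and the CLDN2 call without WTAP array 4 (0.0527, limma, over the alternatives 0.00386 to 0.0527). For 3 genes named after their values were seen the log2 fold changes were 0.21 (CDH1, E-cadherin, adjusted p = 0.277), -0.27 (CDH2, N-cadherin, adjusted p = 0.299) and -0.08 (EPCAM, adjusted p = 0.712, limma). Of 12 squamous and basal keratinocyte genes, 5 rose and 1 fell (6 when adjusted over the list alone), led by KRT13 and by S100A9 (1.58), a calcium-binding protein of inflamed epithelia. Of 12 carcinoembryonic antigen, trefoil and secreted mucosal proteins, 5 rose and 0 fell (5 when adjusted over the list alone), among them CEACAM6 (1.34) and SCGB1A1 (0.90, detected on 1 mock array). Cholangiocyte markers gave 5 higher and 0 lower of 18 (5 when adjusted over the list alone), with PROM1 at 1.65 beside MUC1.

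Genes of the matrix and of adhesion to it changed in both directions. Among 18 laminins, collagens and basement membrane genes 4 rose and 5 fell (9 when adjusted over the list alone). COL4A1, a chain of basement membrane collagen, was not detected on any mock array and was at least 3.35-fold higher (limma adjusted p = 7.46e-05), and COL4A5 fell by 1.25. COL4A1 lies on chromosome 13, in a block with a median of 0.59. Of 16 integrins 2 rose and 3 fell (8 when adjusted over the list alone, and 4 and 4 without background correction, with an offset of 50 or in the authors' processed table), where ITGA2 fell by 1.37 and ITGAV rose by 0.83. The ITGAV call was lost without WTAP array 4 (adjusted p = 0.0525, limma, over 18 alternatives 0.00100 to 0.0525). S100 proteins had 3 higher and 1 lower of 12 (5 when adjusted over the list alone), and 2 of each after the subtraction of neighbouring genes, with S100P, not detected on any mock array, at least 2.19-fold higher (limma adjusted p = 0.000508).

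Inflammatory and growth factor genes held the largest groups of falls. Of 45 targets of NF-kB, cytokines and chemokines, 17 fell and 5 rose (25 when adjusted over the list alone). IL1A fell by 2.25 (11.63 ± 0.15 against 9.38 ± 1.03, SD, n = 3 each, limma adjusted p = 0.00974) and the chemokine CCL20 by 1.56. WTAP array 6 lay nearest to the mock arrays for IL1A: without it IL1A fell by 2.83, IL1B fell by 2.12 and the list as a whole passed in camera (adjusted p = 0.00946, over 19 alternatives 0.00946 to 0.805), as it did under no other alternative. With all arrays and an estimated correlation that list had an adjusted p of 0.805. IL1B, named after its values were seen, fell by 1.53 (adjusted p = 0.0416, limma), a call lost without mock array 4, 5 or 6 (0.0920, 0.0862 and 0.105), without WTAP array 4 or 5 (0.130 and 0.106), with no filter on dim probes (0.0702), with a trended and robust variance (0.120) and after the subtraction of neighbouring genes (0.0667, over 18 alternatives 0.000478 to 0.130). Of 49 interferon-stimulated genes 6 fell and 4 rose (14 when adjusted over the list alone). These counts were 13 and 6 with no background correction and in the authors' processed table, 11 and 4 with an offset of 50, and 10 and 2 with median scaling, but 4 and 4 after the subtraction of neighbouring genes. As a whole the interferon list passed downward in camera without mock array 6 (adjusted p = 0.0177), without WTAP array 5 (0.00249) and with no filter on dim probes (0.0197). With all arrays its adjusted p in camera was 0.0806, and 0.815 with an estimated correlation (over 19 alternatives 0.00249 to 0.815). CXCL10 fell by 1.59 and IFI44L fell by 1.51. The IFI44L call (adjusted p = 0.0419) was lost without mock array 4, 5 or 6 (0.0961, 0.119 and 0.0508), without WTAP array 4 or 6 (0.102 and 0.0657), with no filter on dim probes (0.0708), with a trended and robust variance (0.0966) and after the subtraction of neighbouring genes (0.0602, limma, over 18 alternatives 0.00496 to 0.119). Of 49 growth factor ligands, receptors and their feedback genes 17 fell and 8 rose (27 when adjusted over the list alone), where DUSP5, a phosphatase that dampens ERK signalling, fell by 1.81 and FGF2 fell by 1.64. A second FGF2 probe had a log2 fold change of -0.92 (adjusted p = 0.0971, limma). Hypoxia and glycolysis genes had 9 lower and 2 higher of 37 (13 when adjusted over the list alone), and the 2 that rose were LOX and the carbonic anhydrase CA12 (1.28). After the subtraction of neighbouring genes 11 of the inflammatory genes, 16 of the growth factor genes and 3 of the hypoxia genes were lower.

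More cell cycle genes rose than fell, though neither list passed as a whole in the main setting (camera adjusted p = 0.068 for each, over 19 alternatives 0.0155 to 0.805 for mitosis and 0.00678 to 0.805 for replication, the highest with an estimated correlation). Of 55 genes of G2/M and mitosis 8 rose and 3 fell (11 when adjusted over the list alone), among them NUF2, a kinetochore protein (0.88), and CKAP2 (0.87), which lies on chromosome 13. Of 48 DNA replication genes 5 rose and 2 fell (4 when adjusted over the list alone), led by E2F2 (1.20) and the cyclin CCNE2 (1.12). Mitosis genes counted 13 higher and 4 lower, and replication genes 11 and 3, with no background correction and in the authors' processed table. With an offset of 50 these counts were 11 and 4, and 9 and 2. After the subtraction of neighbouring genes, 4 mitosis genes and 3 replication genes were higher and 0 of either were lower. Of all 11586 tested genes, 1218 were higher and 1148 lower in the main setting, and 803 and 851 after the subtraction. Replication genes thus rose about as often as all genes in the main setting, and after the subtraction both lists did. As whole lists, however, both passed upward in camera after the subtraction (adjusted p = 0.0155 for mitosis and 0.0181 for replication). With an estimated correlation after it neither passed (0.842 for each, camera). Targets of p53 gave 7 lower and 2 higher of 23 (11 when adjusted over the list alone), with TP53I3 falling by 1.30 and CDKN1A, the p21 cell cycle inhibitor, by 1.13. The second TP53I3 probe fell by 0.51, and the CDKN1A call was lost without mock array 6, WTAP array 4 or WTAP array 5 (adjusted p = 0.0580, 0.0679 and 0.0536, limma, over 18 alternatives 0.00141 to 0.0679). Of 33 apoptosis regulators 6 fell and 1 rose (7 when adjusted over the list alone): CASP1 fell by 1.01 and HRK rose by 1.43. Of 38 genes of the unfolded protein and integrated stress response 6 fell and 2 rose (8 when adjusted over the list alone). SLC7A11, the cystine transporter, was not detected on the arrays labelled WTAP and was at least 2.67-fold lower (limma adjusted p = 0.00066), and CTH fell by 0.92. The 2 other CTH probes had log2 fold changes of -0.43 and -0.58 (adjusted p = 0.158 and 0.192, limma).

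Targets of NRF2 with glutathione and metallothionein genes gave 5 higher and 7 lower of 34 (15 when adjusted over the list alone), and 6 higher and 12 lower with no background correction and in the authors' processed table. AKR1C2 rose by 2.36 and GSTM1 by 1.83 (detected on 1 mock array), both members of families of near-identical genes and so uncertain as to the copy. Xenobiotic metabolism and transport genes gave 4 higher and 0 lower of 18 (6 when adjusted over the list alone), and 2 higher and 0 lower after the subtraction of neighbouring genes, with ALDH3B1 at 1.05 and ABCC4, on chromosome 13, at 0.81. In the Wnt pathway 6 of 21 rose and 3 fell (11 when adjusted over the list alone), including the receptors FZD7 (1.61) and FZD2 (0.96). The second FZD7 probe had a log2 fold change of 0.25 (adjusted p = 0.171, limma). In the TGF-beta and BMP pathway 7 of 28 rose and 4 fell (13 when adjusted over the list alone), led by the inhibitory SMAD6 (1.69) and the activin subunit INHBB (1.53). In the Notch and Hedgehog pathways 3 of 16 rose and 3 fell (6 when adjusted over the list alone). HES2 fell by 1.69 and HHIP, a Hedgehog-binding protein not detected on the arrays labelled WTAP, was at least 2.34-fold lower (limma adjusted p = 0.00555). The counts became 2 higher and 3 lower with median scaling, and 1 higher and 3 lower after the subtraction of neighbouring genes. The median of this list was 0.0041, its mean -0.11 and its camera direction down.

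Few genes of RNA methylation, splicing and translation passed the threshold. Of 16 members of the m6A methyltransferase complex with its erasers and readers, 1 rose, the reader YTHDF3, by 0.49 (adjusted p = 0.0316, limma), and 0 passed when adjusted over the list alone, with 1 at an unadjusted p under 0.05. The YTHDF3 call was lost with median scaling (0.0532), without mock array 4, 5 or 6 (0.0542, 0.0629 and 0.0926), without WTAP array 4 or 6 (0.104 and 0.0554) and after the subtraction of its neighbours on chromosome 8 (0.295, limma, over 18 alternatives 0.00832 to 0.295). Of 60 splicing factors 4 rose and 1 fell (1 when adjusted over the list alone), with 9 higher and 1 lower with no background correction and in the authors' processed table and 7 and 1 with an offset of 50. As a whole this list passed upward in camera only after the subtraction of neighbouring genes (adjusted p = 0.0221, against 0.114 before, over 19 alternatives 0.0221 to 0.805), and not with an estimated correlation after it (0.842). Among those that rose were PRPF3 (0.85) and SRSF6 (0.62), and the SRSF6 call was lost without mock array 5 or 6 (adjusted p = 0.0691 and 0.0719, limma, over 18 alternatives 0.00179 to 0.0719). Of 63 ribosomal proteins 2 rose and 4 fell (2 when adjusted over the list alone), with RPL29 falling by 0.67 and RPL34 by 0.64; the median of this list was 0.0029, its mean -0.02 and its camera direction down. Oxidative phosphorylation gave 2 higher and 3 lower of 43 (2 when adjusted over the list alone), and 1 higher and 0 lower after the subtraction of neighbouring genes, with SDHA at 0.68 and ATP5F1C falling by 0.73. Histone genes gave 2 higher and 3 lower of 25 (5 when adjusted over the list alone), with H2BC9 at 0.68 and H2AJ falling by 0.76, and copies of histone genes can cross-hybridise. After the subtraction of neighbouring genes the calls of RPL34 on chromosome 4, ATP5F1C on chromosome 10 and H2AJ on chromosome 12 were lost (adjusted p = 0.286, 0.636 and 0.164, limma). The RPL34 call was also lost without WTAP array 4 (0.0539) and the H2AJ call without mock array 5 (0.0505, limma). Over 18 alternatives the adjusted p of RPL34 was 0.000533 to 0.286, that of ATP5F1C 0.000116 to 0.636 and that of H2AJ 0.00112 to 0.164 (limma). Of 28 cholesterol and fatty acid synthesis genes 0 passed in limma, over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05, and 2 were higher and 2 lower with no background correction and in the authors' processed table.

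Few markers of other cell types were tested, which limits the number of calls. Of those on the arrays, 7 of 15 fibroblast and stromal, 8 of 20 leukocyte, 3 of 14 endothelial and 4 of 23 hepatocyte markers were tested. Among all tested genes 20.4% changed, so counts this small cannot show that a list changed less than other genes. Of 7 fibroblast and stromal markers, COL1A1 rose by 0.74 and MFAP5 fell by 0.40 (3 when adjusted over the list alone), and the MFAP5 call (adjusted p = 0.0461) was lost under 14 of 18 alternatives (adjusted p 0.0333 to 0.279, limma). That included leaving out mock array 4, 5 or 6 (0.0665, 0.140 and 0.105) or WTAP array 4, 5 or 6 (0.0695, 0.130 and 0.0667), and without background correction, with an offset of 50 or in the authors' processed table the counts were 2 higher and 0 lower. Of 8 leukocyte markers 0 passed in limma by either adjustment, with 1 at an unadjusted p under 0.05, and of 3 endothelial markers 0 passed, with 0 at an unadjusted p under 0.05. Among 4 hepatocyte markers CPS1 fell by 0.83 (2 when adjusted over the list alone), a call lost without mock array 5, mock array 6 or WTAP array 4 (adjusted p = 0.0677, 0.0628 and 0.0746, limma, over 18 alternatives 0.00382 to 0.0746). Antigen presentation had 1 gene of 18 lower, TAP2, which fell by 0.55 (adjusted p = 0.0441), with 0 when adjusted over the list alone and 3 at an unadjusted p under 0.05. The TAP2 call was lost without mock array 4, 5 or 6 (0.122, 0.0669 and 0.0868), without WTAP array 4 or 5 (0.121 and 0.122) and with no filter on dim probes (0.0689, limma, over 18 alternatives 0.0110 to 0.122). A second TAP2 probe had a log2 fold change of -0.66 (adjusted p = 0.0105, limma over all detected probes). Cancer testis antigens had 2 of 5 lower, SPANXA1 and SPANXC (fell by 2.74), which share near-identical sequence (2 when adjusted over the list alone).

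**Figure D4:**
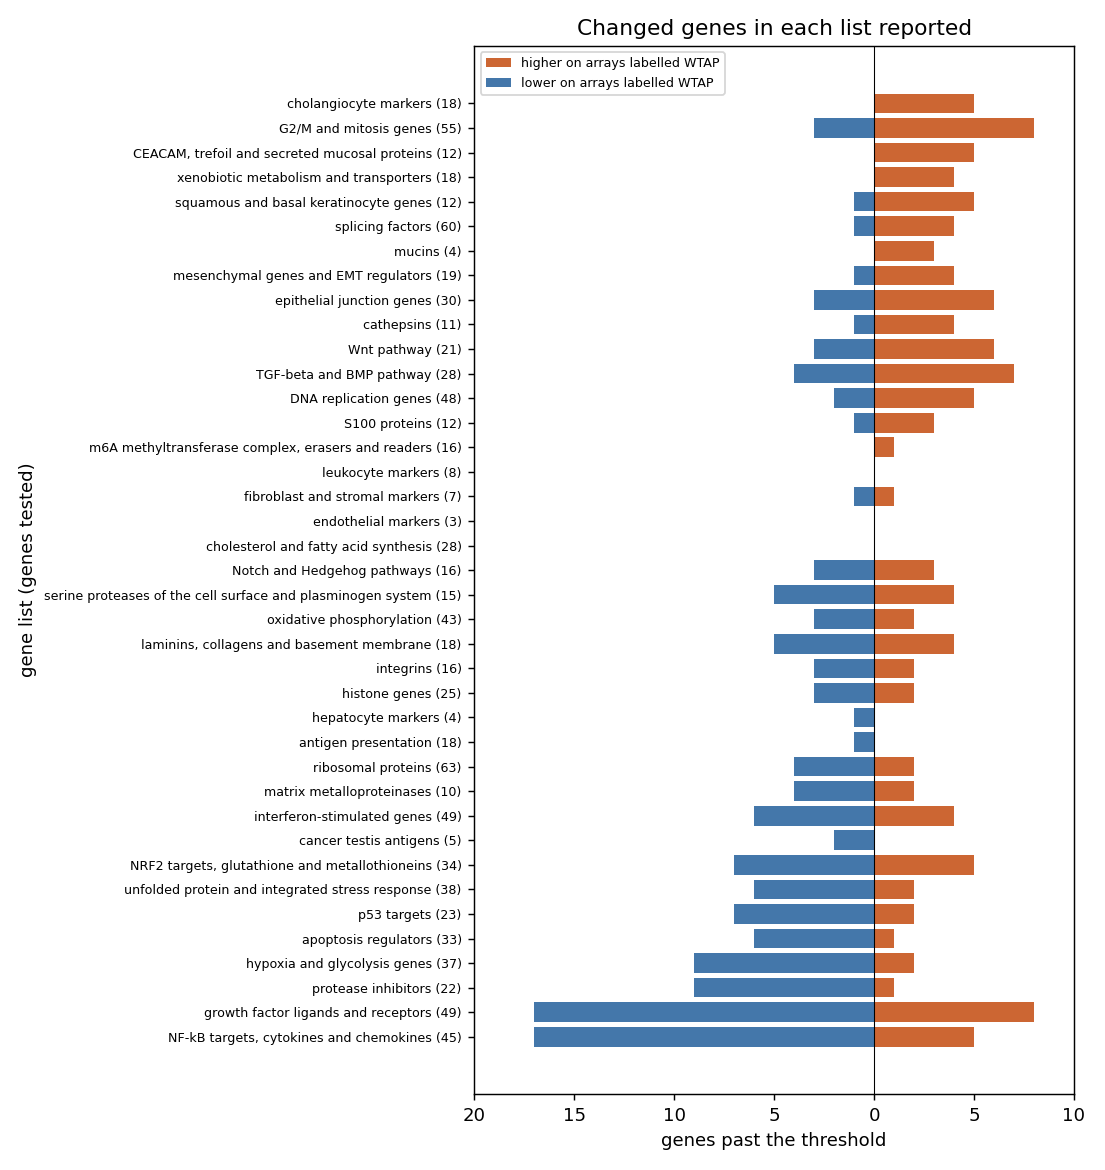
Number of genes past an adjusted p of 0.05 in each gene list reported (vertical axis, with the number tested in brackets), drawn to the right where higher and to the left where lower in the cells labelled WTAP (horizontal axis, number of genes). The inflammatory and growth factor lists have the most lower genes, 17 each, and the growth factor and mitosis lists have the most higher ones, 8 each.

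As whole lists, 0 of the 37 with at least 5 tested genes passed in camera, which compares a list's genes with all others, while 9 had an unadjusted p under 0.05. Without 1 array up to 3 passed: 2 without mock array 4 or WTAP array 6, 3 without mock array 5, mock array 6 or WTAP array 5, and 0 without WTAP array 4. The lowest adjusted p, 0.0656, was shared by the protease inhibitors (down), the carcinoembryonic antigen and mucosal list (up) and the squamous and basal list (up). With an estimated correlation in place of the preset one 0 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.805. In fry, which tests whether a list's genes move on balance one way without comparing them with other genes, 6 lists passed at an adjusted p of 0.0488: these 3 and the xenobiotic, unfolded protein and apoptosis lists.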

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

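The tests of probe saturation, of whether both sets of arrays hold the same cells, of WTAP probe position, of GC content, of a uniform shift of neighbouring genes, of the second vimentin probe and of vimentin's neighbourhood were chosen only after the results were seen.

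Probes without a gene name, which no comparison above uses, also differed between the lines. Of 679 such probes detected on at least 3 arrays, 64 were higher and 61 lower in the cells labelled WTAP than in mock cells (limma, adjusted p under 0.05), the largest change being a log2 fold change of -3.28 (adjusted p = 5.09e-06). Of the 92 probes that the authors' processed table lacks, 0 passed in limma, with 6 at an unadjusted p under 0.05. What these probes measure was not tested.

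The 6 arrays can be parted into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2366 changed genes and the highest of the others 0, and it gave 467 genes at least 2-fold changed and the highest of the others 0, so that 1 of 10 splits gave as many of either. Among the 4 splits that part every pair of arrays with the same number, the other 3 exchange the groups of 1 pair and gave 0 genes each in limma. For gene lists in camera the real split gave 0, so every split had to give at least as many and the comparison decides nothing. The highest of the others gave 9, when mock array 4 and WTAP arrays 4 and 6 were set against the rest. That split gave 0 genes. Every split but the real one has arrays of both groups on each side. Part of the group difference then stays between the sides, and the rest adds to the spread within them. Whether the 9 lists reflect that remainder, a structure of the samples or too low a preset correlation was not tested.

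No increase of WTAP was seen on its 2 detected probes (log2 fold changes 0.06 and -0.01), although the cells are labelled as overexpressing it. Saturation is argued against, since the brighter probe lay at most at the 81.7th percentile of signals on a mock array. That both sets of arrays hold the same cells is argued against as well, since the lowest correlation within a group exceeded the highest between groups by 0.012. It stays open whether the probes lie outside the cloned part of WTAP, since the position is known for 0 of the WTAP probes, and whether the cells gained any WTAP transcript was not tested otherwise. Until then the changes may belong to the WTAP construct or to other differences between 2 separately derived lines.

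The number of changed genes may in part reflect differences in copy number between the lines, as the log2 fold changes of neighbouring genes correlated at 0.209, against -0.03 to 0.03 in 1000 random gene orders. The scaling is argued against as the cause, since the lowest count under 4 other scalings was 2332. A shift that follows the GC content of whole chromosomes is argued against too. The median of chromosome 13 exceeded that of chromosome 4 by 0.72 although both are poor in GC. Both medians were known when this comparison was chosen, and the GC content of genes or probes was not examined. A uniform shift of neighbouring genes is argued against as the whole cause, since 1654 genes passed after it was subtracted. DNA was not analysed here, so copy number and shared regulation of neighbouring genes were not separated. Overexpression of WTAP, the difference that the labels name, stays open and untested, since it coincides with the derivation of the lines.

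Vimentin fell 29.8-fold in the cells labelled WTAP. A faulty probe is argued against, since the other probe fell by 6.52, and so is the shift of its neighbourhood on chromosome 10 as the whole cause, since VIM fell by 4.23 after its subtraction. Stromal cells mixed into the mock cultures are argued against, since 1 of 7 fibroblast and stromal markers was lower, 1 was higher, and lumican (LUM) had a log2 fold change of 1.03 that did not pass (limma adjusted p = 0.0632). A change of vimentin in the tumour cells themselves, from WTAP or from selection of the line, is a hypothesis these arrays leave open.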

How the results depend on the processing

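The subtraction of neighbouring genes was chosen after seeing the data. WTAP stayed short of the threshold under every alternative run (log2 fold change 0.017 to 0.092). The number of changed genes was 1345 to 2245 without 1 array, 958 at an adjusted p under 0.01, 1654 after the subtraction of neighbouring genes and 1979 to 3020 under the others. With median scaling 43.3% of changed genes were higher, against 51.5%, and the median of all genes moved to -0.03. The number of genes changed at least 2-fold was 184 with no background correction, which leaves the background in both groups and so shrinks folds, 175 in the authors' processed table, 408 to 520 without 1 array and 320 to 598 otherwise. Gene lists past the threshold, 0 in camera, were 3 with median scaling, 6 with no filter on dim probes (40 tested in place of 37, so that 1 of the 6, the mucins, was too short to test before), 6 in fry, 5 after the subtraction of neighbouring genes and 0 to 3 without 1 array. The cause of the moves in the list counts and in the authors' table was not tested. With an estimated correlation 0 lists passed before and after that subtraction (lowest adjusted p 0.805 and 0.842). With the replicate block, which follows the numbers of the titles, 2584 genes changed, 475 at least 2-fold, and 0 lists passed. Of the named genes only MFAP5 lost its call with that block (adjusted p = 0.0669, limma, over 18 alternatives 0.0333 to 0.279). Of 118 genes other than WTAP followed through the alternatives, 98 kept their direction and side of the threshold in every alternative run. The other 20 lost their call in some, 75 times in all, and 0 reversed. These 118 genes were mostly chosen for large changes and do not stand for all calls. Of the 2366 calls of the main setting, 1300 (without WTAP array 4) to 1863 (without WTAP array 6) were kept without 1 array. After the subtraction of neighbouring genes 1431 were kept. A block for the chip was not run, as no chip is named. Signal over background limits dim genes: 51.5% to 55.7% of probes were detected per array, and their fold changes are understated.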

Other observations

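The MAPK test and the genes named in this part were chosen after their values were seen.

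Single genes that belong to no list also differed between the lines, and the families of these genes were not tested. The trypsinogen genes PRSS1, PRSS2 and PRSS3 fell by 2.44, fell by 2.22 and fell by 1.58 in the cells labelled WTAP, though near-identical copies keep the gene uncertain (limma adjusted p = 0.000497, 0.000958 and 0.000144). The uroplakin genes UPK2 and UPK3B rose by 2.05 and 1.94, each detected on 2 mock arrays (adjusted p = 0.00700 and 0.00807, limma). The fetal globin gene HBG1 and the globin pseudogene HBBP1 rose by 2.12 and 1.85, and probes of these related genes can cross-hybridise (limma adjusted p = 0.00109 and 0.000144). TLR4, a receptor for bacterial lipopolysaccharide, fell by 2.46 and was detected on 1 array labelled WTAP (limma adjusted p = 0.000958). All 3 arrays of a group lay beyond those of the other for each of these genes.

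On chromosome 10, where most changed genes fell, LOXL4, AKR1C2 and HTRA1 rose, by 2.75, 2.36 and 1.52, while the medians of their blocks were -0.45, -0.67 and -0.37 (gene order of assembly GRCh38.p14).

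The fall of DUSP5 led to the hypothesis that lower output of the MAPK pathway may underlie lower genes induced by ERK signalling. Of 10 output genes, 5 fell (DUSP6 by 1.20, EPHA4 by 1.14, DUSP4 by 1.01, ETV5 by 0.80 and ETV4 by 0.71), EPHA2 rose by 0.71 and 4 did not pass. The 6 that passed are also in the growth factor list, so this is no separate evidence. The 4 that did not pass had log2 fold changes of -0.40 (PHLDA1, limma adjusted p = 0.0512), -0.34 (SPRY4), -0.25 (CCND1) and -0.14 (SPRY2). With EPHA2 higher and these 4 short of the threshold, the hypothesis stays open. The ETV5 call was lost without mock array 4 or 6 (adjusted p = 0.0661 and 0.0567, limma, over 18 alternatives 0.00224 to 0.0661) and the EPHA4 call without WTAP array 4 (0.0569, limma, over the alternatives 0.00335 to 0.0569). EPHA4 was detected on 1 array labelled WTAP, and the second ETV5 probe had a log2 fold change of -0.70 that did not pass (limma adjusted p = 0.106). Phosphorylated ERK was not analysed here.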
